A study of Arabidopsis thaliana with 12 samples.

How the data were processed

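RNA from whole Arabidopsis thaliana seedlings (ecotype Columbia) was hybridised to 12 single-colour Affymetrix ATH1 arrays, 3 in each of 4 groups. The seedlings carried either an empty vector or the gene MINI ZINC FINGER 1 under the constitutive 35S promoter (MIF1OE), and grew for 7 days in light or in darkness. Per the labels' protocols, seeds were stratified for 2 days and grown at 22 °C on medium with 50 µg/mL hygromycin, and resistant seedlings were harvested. Light-grown plants had 16 h of light and 8 h of darkness. Dark-grown plants had 2 h of light to induce germination.

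The deposited values are linear probe set intensities that the authors computed with GCOS, the Affymetrix expression software, per the submitters' processing notes, whose version is not given in the sources used here. The mean intensity after trimming 2% at each end was 150.01 on every array, and the highest mean was 1.00002 times the lowest. By a rule set beforehand, the authors' scaling was therefore kept and no further normalization was applied. Equal trimmed means reflect that scaling, and do not show that the arrays are comparable in other respects. The deposited table held 22810 probe sets and no detection calls were used. On arrays, the number of arrays limits the precision. Median intensity per array lay between 57.4 and 70.4.

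From these intensities log2(value + 7) was computed, the pseudocount being set from the median of all values (65.2). Fold changes are on this scale, which understates the change of dim probe sets. The 64 control probe sets and the 6824 dimmest of the other 22746 (below the 30th percentile of the mean over all arrays) were left out, so 15922 were tested. Each comparison was a contrast in limma 3.58.1 (R 4.3.3), with lmFit and eBayes on all 12 arrays and 4 group means, sharing 1 estimate of spread per probe set (8 residual and 4.08 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over all probe sets tested, and the threshold was 0.05. The contrasts were MIF1OE against vector in light, the same in darkness, the difference between these (the interaction), and dark against light in each genotype. Standard errors (SE) are those of limma after moderation. They pool the spread of all 4 groups, so an SE given for darkness also holds the spread of the light arrays, and the reverse.

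Genes were named through the platform annotation and then by Entrez identifier through a RefSeq gene table of assembly TAIR10.1, from which no coordinates are printed because the deposited table names no build. Of the 22746 probe sets, 13513 named 1 gene, 503 named several and 8730 were unnamed here. 13436 matched the gene table. Among probe sets tested, 54.9% named 1 gene. No probe set was named as MIF1, so the level of the transgene cannot be reported by name. A gene with several probe sets was represented in gene lists by the brightest.

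Choices described so far, 27 gene lists, the rule for named genes and the alternative settings were set before the data were examined. Named genes were MIF1, the 10 largest rises and 10 largest falls in light and in darkness among called probe sets with non-overlapping groups, the 5 largest in each direction for the interaction and for dark against light in vector seedlings, and list members (up to 4 called and 2 not called per list for MIF1OE against vector, up to 3 called for dark against light). Of 438 listed genes, 4 were left out because the tables gave their locus another symbol, and 51 were measured by a named probe set among those tested. Only 6 lists had the 3 members needed for a test and 7 had none. The labels call the samples of a group biological replicates. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, and with an estimated correlation as an alternative. A further 8 lists and 38 families formed from shared symbol stems were examined after the data had been seen.

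The vector seedlings came from 3 independent transformed lines (numbers 1, 4 and 7). MIF1OE seedlings came from line 124 (replicates 1 and 2) and line 127 (replicate 3), so 2 of 3 samples share a line. Light- and dark-grown samples of the same source are paired by line, and within line 124 by the replicate number in the labels. Vector and MIF1OE samples carry no shared number. The deviations from group means of the 6 same-source pairs correlated across probe sets with r between 0.233 and 0.339. The pairing was therefore entered as an alternative: a fixed replicate block for the interaction and for dark against light, and a random block for MIF1OE against vector. No pair of the 66 pairs of arrays held identical values.

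The fit was tested on simulated arrays with the real mean and pooled spread of each probe set and 200 changed probe sets among 15922. In the light comparison 92.4% of 4-fold changes and 44.8% of 2-fold changes were called. In the dark comparison the shares were 93.9% and 56.7%, and in the interaction 63.6% and 13.4%. For dark against light they were 87.9% and 52.2% in vector seedlings and 84.8% and 38.8% in MIF1OE seedlings. Of 1.5-fold changes 17.9%, 8.96%, 0%, 13.4% and 5.97% were called in these 5 comparisons, so small changes were mostly missed in these simulations. False calls made up 7.21%, 9.40%, 8.93%, 6.42% and 1.15% of the calls in these single runs, and on average 5.20%, 5.36%, 4.88%, 4.97% and 4.95% over 100 runs each (SE 0.200 to 0.311, single runs up to 15.8%). The simulated probe sets vary independently, which real ones do not. All simulated groups also had equal spread, whereas the real light arrays spread more than the dark ones (residual SD 0.380 against 0.310). The simulated shares of false calls therefore do not cover the effect of pooling unequal spreads. With 200 changed probe sets, they also differ from the dark comparison, where 2052 were called. Alternatives covered normalization, pseudocount, filter, spread estimate, threshold, blocks, lines and leaving out each array, and some were added after the data had been seen.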

Results

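Transcript levels were measured in 7-day-old seedlings that overexpress MIF1, a small protein with a zinc finger but no homeodomain, and in seedlings with an empty vector. Each genotype was grown in light and in darkness, giving 4 groups of 3 arrays. Correlations between arrays of a group ran from 0.922 to 0.944 for light-grown vector seedlings, 0.941 to 0.962 for light-grown MIF1OE, 0.955 to 0.961 for dark-grown vector and 0.957 to 0.959 for dark-grown MIF1OE seedlings. The first principal component held 49.1% of the variance and separated light from dark, and the second held 19.4% and placed every MIF1OE array below every vector array. No probe set carried the name MIF1. The largest change in light was that of a probe set unnamed here (log2 fold change 5.57, SE 0.32, limma adjusted p = 1.188e-05, 47.5-fold), which was also higher in darkness (4.36, SE 0.32). Another unnamed probe set changed most in darkness (log2 fold change 6.42, SE 0.36). Of the 20 largest changes, 14 in light and 18 in darkness had no single gene name (unnamed or naming several genes), so the named genes cover only part of the response.

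**Figure D1:**
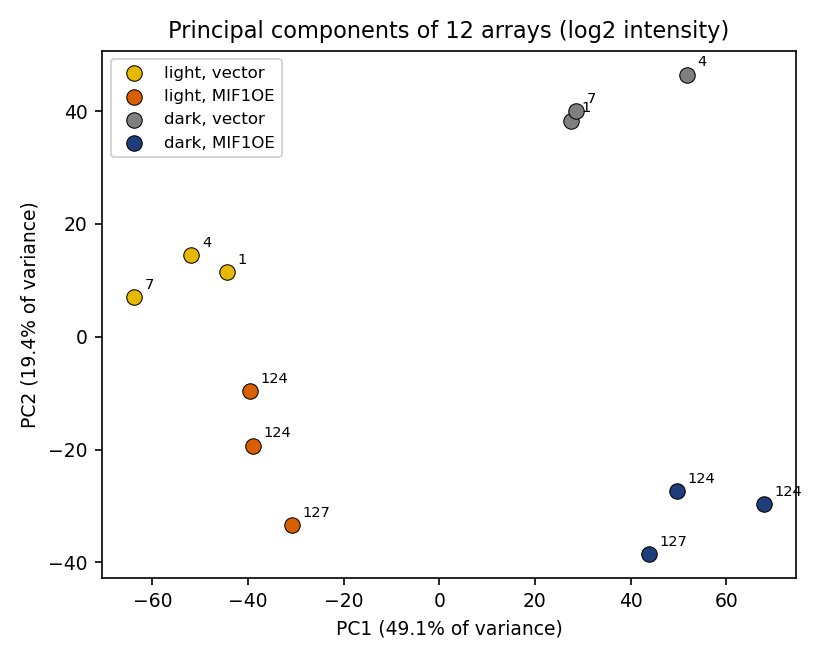
Principal components 1 and 2 of log2 intensity over 15922 probe sets, 1 point per array, coloured by group and marked with the number of the transgenic line. Light and dark arrays lie apart along the first axis (49.1% of variance) and MIF1OE arrays lie below vector arrays along the second (19.4%).

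The first comparison asked which transcripts MIF1 overexpression alters in light-grown seedlings. ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle that seedlings use while they consume stored oil, rose most among named genes, by 4.11 on the log2 scale (SE 0.40, n = 3 per group, limma adjusted p = 5.221e-04). OSM34, an osmotin, was higher by 2.42 (SE 0.30), APS4, an ATP sulfurylase, by 2.23 (SE 0.24), and AT5G10210 by 3.02 (SE 0.36). The largest named fall was that of ECS1 (log2 fold change -3.82, SE 0.61). AT1G22690, of the gibberellin-regulated GASA family, fell by 2.56 (SE 0.32) and AT3G56060 fell by 1.97 (SE 0.18). Other rises included AT1G12010, an ACC oxidase of ethylene synthesis (3.19, SE 0.50), the jacalin lectin AT3G21380 (3.02, SE 0.52), the beta-glucosidase BGLU19 (2.93, SE 0.47), the class V chitinase ChiC (2.24, SE 0.38), AT5G39520 (2.22, SE 0.35) and AT4G16260 (2.2, SE 0.40). Other falls were those of AT4G38690 (-2.19, SE 0.35), the methionine sulfoxide reductase MSRB6 (-1.98, SE 0.41), AT5G25840 (-1.91, SE 0.30), AT1G06830 (-1.88, SE 0.38), AT1G04800 (-1.76, SE 0.37), BGLU33 (-1.72, SE 0.32) and AT1G51805 (-1.63, SE 0.32).

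In all, 157 of 15922 probe sets passed in light (105 higher, 52 lower), and 138 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 1833. The count was 57 with only the light arrays in the fit (49 higher, 8 lower) and 103 with a 50th percentile filter (77 higher, 26 lower). In fits chosen after the data had been seen it was 45 with MIF1OE line 124 alone, 97 with line 127 alone, 329 with the first residual component as a covariate and 412 with sets of arrays that deviate together as a block. Leaving out single arrays gave 93 (without light vector replicate 2) and 67 (without light MIF1OE replicate 1). Without light MIF1OE replicate 2 the count was 266 (138 higher, 128 lower). Without light MIF1OE replicate 3, the only light array of line 127, it was 44 (40 higher, 4 lower). Of the 20 named genes past the threshold, only ICL, AT5G10210, OSM34, APS4, AT1G22690 and AT3G56060 (6 genes) stayed past it under every other setting chosen beforehand, stricter thresholds apart. The calls of the other 14 each ended without at least 1 of the light arrays of vector replicates 1 to 3 or MIF1OE replicates 1 and 3 (adjusted p up to 0.188). Of these 14, 11 were also lost under other settings: 10 with only the light arrays in the fit, where their log2 fold changes are unchanged (adjusted p up to 0.213), 4 without a filter, 4 with values floored at the pseudocount, 2 with line as a random block, and 1 each with median-centred arrays, the 50th percentile filter and the larger pseudocount.

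No member of the fixed lists passed over all genes in light. Expansins, which loosen cell walls, had a median log2 fold change of -0.45 over 9 members, with 2 lower when adjusted over the list alone, and the list shifted down in camera (adjusted p = 0.0169; adjusted p = 0.274 with an estimated correlation). EXPA8 stood at -2.60 (SE 0.78) and EXPB3 at -1.06 (SE 0.54). The 9 photosynthesis genes had a median of -0.30 (camera adjusted p = 0.0384; adjusted p = 0.552 with an estimated correlation), with none past the threshold when adjusted over the list alone. PSBW was at -0.38 (SE 0.25) and LHCB4.2 at -0.36 (SE 0.40). The 3 measured SAUR and GH3 auxin-response genes, all GH3 genes, had a median of 0.59 (camera adjusted p = 0.0307; adjusted p = 0.274 with an estimated correlation), with 1 higher when adjusted over the list alone. GH3.17, an enzyme that conjugates auxin, was at 1.12 (SE 0.29) and GH3.3 at 0.59 (SE 0.52). The 3 gibberellin receptor genes had a median of 0.50 (camera adjusted p = 0.0439; adjusted p = 0.288 with an estimated correlation), with 2 higher when adjusted over the list alone. GID1B was at 0.63 (SE 0.18) and GID1A at 0.50 (SE 0.20). The 4 list calls became 1 without light vector replicate 1, light MIF1OE replicate 1 or light MIF1OE replicate 2, and 0 without light vector replicate 3 or without the filter. Xyloglucan endotransglucosylases (median -0.09, adjusted p = 0.992) and chlorophyll synthesis genes (median -0.15, adjusted p = 0.386) were not called.

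The second comparison asked the same question in dark-grown seedlings. AT2G28490, a cupin related to seed storage proteins, was 4.95 higher on the log2 scale (SE 0.66, n = 3 per group, limma adjusted p = 0.00104). LEA18, a late embryogenesis abundant protein, was higher by 3.99 (SE 0.70), and AT3G02480, AT3G15670 and AT3G17520 of the same class by 3.89 (SE 0.77), 3.84 (SE 0.87) and 3.66 (SE 0.72). The oleosin AT3G01570 was higher by 3.35 (SE 0.58) and the cupin AT4G36700 by 3.38 (SE 0.68). BGLU19 (4.46, SE 0.47), AT1G23130 (3.88, SE 0.51) and AT1G04560 (3.73, SE 0.67) completed the 10 largest rises. The largest named falls were those of AT4G18970 (-3.98, SE 0.60), AT5G62280 (-3.97, SE 0.71), AT4G37220 (-3.92, SE 0.39), AT3G48970 (-3.52, SE 0.18) and AT4G38690 (-3.50, SE 0.35). AT5G03120, AT5G11420, AT2G05540, AT5G57760 and AT5G44440 followed, with log2 fold changes of -3.35, -3.24, -3.19, -3.14 and -2.94.

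**Figure D2:**
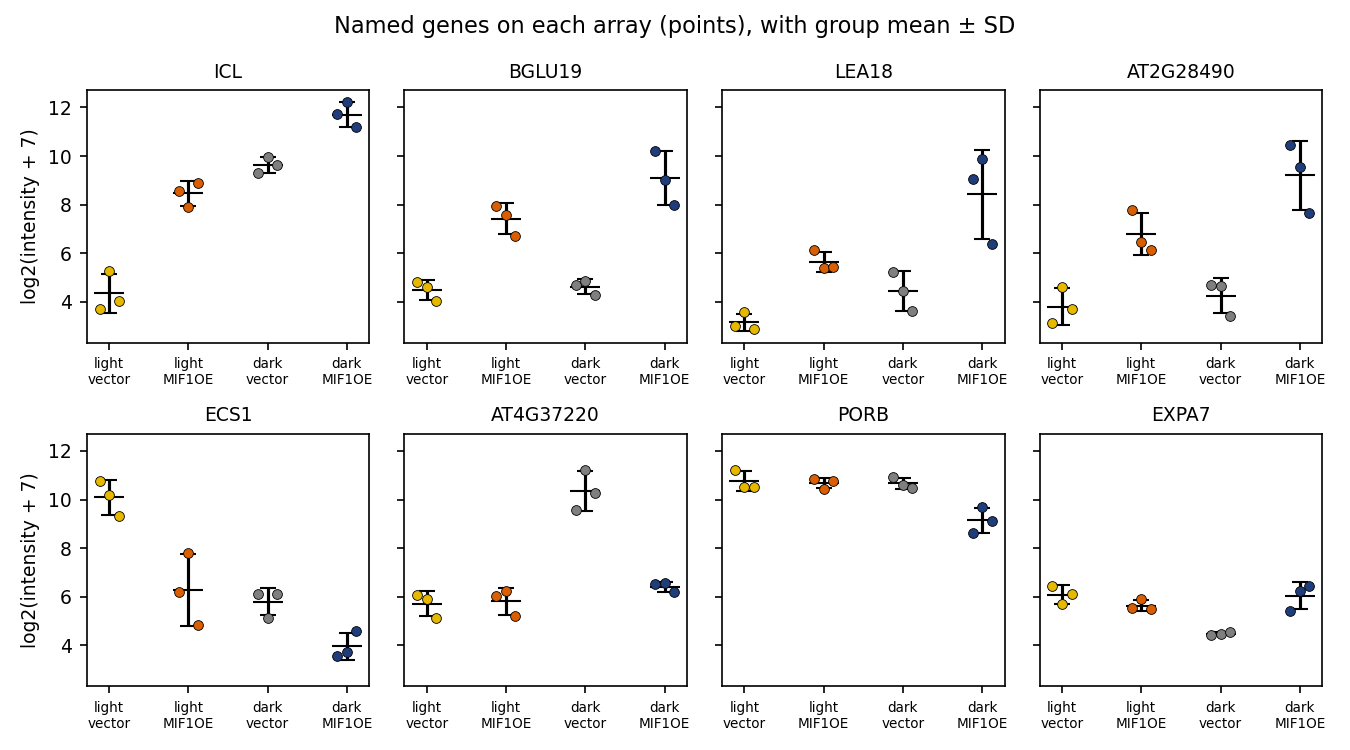
Log2(intensity + 7) of 8 named genes on each of 12 arrays, with points for arrays and bars for group mean and SD (n = 3). ICL was higher in MIF1OE in both conditions, ECS1 was lower in MIF1OE in light, and AT4G37220 and PORB were lower and EXPA7 higher in MIF1OE in darkness.

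Of 3 measured chlorophyll synthesis genes, 2 fell in dark-grown MIF1OE seedlings. PORB, which reduces protochlorophyllide, fell by 1.52 (SE 0.27), CHLM, a magnesium-protoporphyrin methyltransferase, fell by 1.22 (SE 0.17), and CHLI2 was at -0.54 (SE 0.32). With 2 of 3 lower, also when adjusted over the list alone, the list was called down by camera (adjusted p = 0.00918; adjusted p = 0.260 with an estimated correlation). PRK, the Calvin cycle phosphoribulokinase, fell by 1.54 (SE 0.24), the 1 photosynthesis gene of 9 that passed, while LHCB4.2 was at -0.60 (SE 0.40) and SBPASE at -0.56 (SE 0.29). Among 9 expansins, EXPA8 fell by 2.85 (SE 0.78) and EXLA2 fell by 1.63 (SE 0.44), and 3 were lower when adjusted over the list alone. Both calls ended when any 1 dark array was left out (adjusted p up to 0.104 and 0.0928), with floored values or with line as a random block. That of EXPA8 also ended without a filter. The SE of EXPA8 pools light and dark arrays. In darkness EXPA8 lay at 8.70 to 9.09 in vector and 5.75 to 6.44 in MIF1OE seedlings. In light it was more spread, at 6.27 to 8.94 and 3.78 to 7.17. EXPA16 was at -1.15 (SE 0.38) and EXPA4 at -0.97 (SE 0.43). Of 6 xyloglucan endotransglucosylases none passed over all genes and 2 were lower when adjusted over the list alone. XTH32 was at -1.12 (SE 0.44) and XTH16 at -0.98 (SE 0.34). Photosynthesis (median -0.32), expansin (-0.66) and xyloglucan endotransglucosylase (-0.76) lists each had a camera adjusted p of 0.0533 and were not called.

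Few hormone-related genes were measured, so joint movement could not be judged. They were 1 of 17 Aux/IAA, 3 of 25 SAUR and GH3, 3 of 12 gibberellin, and 2 of 26 abscisic acid and dehydration genes. IAA29, an Aux/IAA repressor of auxin response, fell by 2.01 (SE 0.38), and GH3.17 rose by 1.12 (SE 0.29), a call that ended without dark vector replicate 1 or 3 or dark MIF1OE replicate 1 or 3 (adjusted p up to 0.0907). GH3.3 was at -1.01 (SE 0.52) and WES1 (GH3.5) at -0.45 (SE 0.39). COR47, a dehydrin, fell by 0.94 (SE 0.21), a call that ended without dark vector replicate 2 or dark MIF1OE replicate 3 (adjusted p up to 0.0543), while COR15B was at 0.19 (SE 0.26). The gibberellin receptor GID1B was at 0.41 (SE 0.18) and GID1C at -0.47 (SE 0.32). Root hair expansins EXPA7 and EXPA18 rose by 1.56 (SE 0.26) and 1.53 (SE 0.31), whereas PYK10, a beta-glucosidase abundant in roots, was at 0.15 (SE 0.16). The measured genes of cytokinin, ethylene, flavonoid, lignin, circadian, defence, meristem, light-signalling, glucosinolate and lateral root lists did not pass in either condition, each list having only 1 or 2 measured genes. In darkness RR16 was at -0.52 (SE 0.33), RTE1 at -0.18 (SE 0.32), DFR at 0.19 (SE 0.33), HCT at 0.20 (SE 0.19), GI at -0.21 (SE 1.02), HYH at -1.27 (SE 0.62), WRKY53 at 0.17 (SE 0.73), LAS at 0.16 (SE 0.22), BCAT4 at 2.05 (SE 0.95) and LBD16 at 0.37 (SE 0.32).

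In darkness 2052 of 15922 probe sets passed (978 higher, 1074 lower), of which 1036 changed at least 2-fold. The count fell to 1149 and 1074 without dark vector replicates 2 and 3, and to 1302, 1299 and 1052 without dark MIF1OE replicates 1, 2 and 3. In fits chosen after the data had been seen it was 1094 with line 124 alone, 361 with line 127 alone (115 higher, 246 lower, from 1 MIF1OE array), 2968 with the first residual component as a covariate and 3490 with sets of arrays that deviate together as a block. Of the 30 named genes past the threshold, 24 stayed past it under every other setting chosen beforehand, stricter thresholds apart. AT3G15670 and AT5G44440 were among the 6 that did not (adjusted p up to 0.0600 and 0.0651), AT3G15670 without dark vector replicate 3 or dark MIF1OE replicate 1, and AT5G44440 without dark vector replicate 1 or 2.

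**Figure D3:**
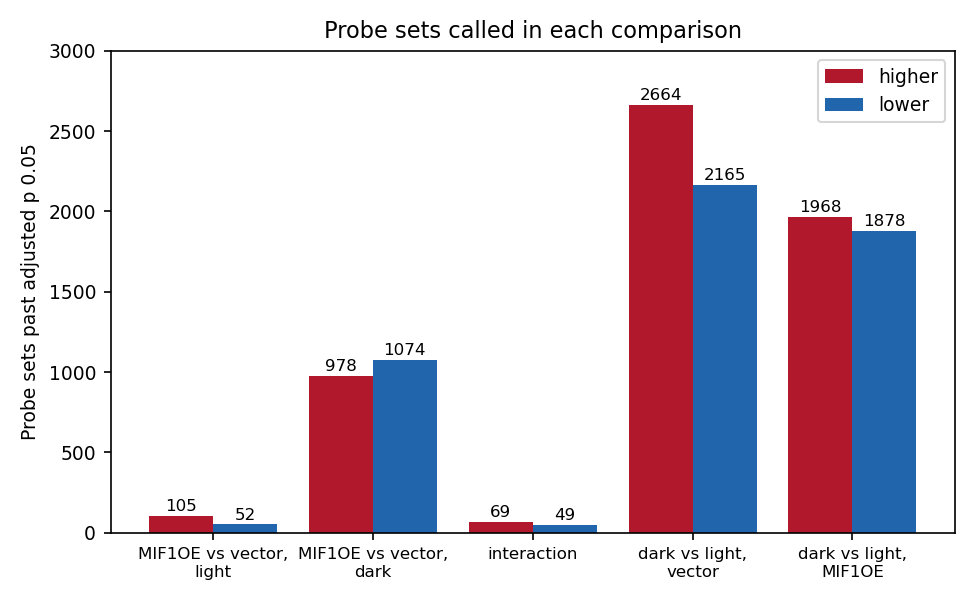
Probe sets past an adjusted p of 0.05 in each comparison, split into higher and lower (bars start at 0). MIF1OE against vector gave 157 in light and 2052 in darkness, the interaction 118, and dark against light 4829 in vector and 3846 in MIF1OE seedlings.

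The light and dark gene sets overlapped. Of the probe sets called in both, 61 were higher in both where independent lists would share 6.45 (Fisher's exact test, one-sided, p = 1.237e-46), and 33 were lower in both where 3.51 would be shared (p = 3.138e-26). Another 4 had opposite directions: 3 were higher in light and lower in darkness, and 1 was lower in light and higher in darkness. Probe sets are not independent replicates. The light and dark samples also come from the same plant sources, whose deviations correlated with r between 0.233 and 0.339. Part of the overlap and of the shared signs may come from the sources, which these expected counts and p-values leave out. Each same-source pair also lies within 1 set of arrays that deviate together across genotypes (r 0.253 to 0.541 within a condition, sets drawn from the residuals). Source and set therefore cannot be told apart. A deviation shared equally by both genotypes would cancel between MIF1OE and vector. BGLU19 was among the 10 largest named rises and AT4G38690 among the 10 largest named falls in both conditions. Of the 157 light calls, 144 (91.7%) had the same sign in darkness, and 41 of these were larger there, though they were selected on their light values.

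The interaction asked whether the effect of MIF1OE differed between darkness and light, and 118 probe sets passed (69 with a higher dark than light effect, 49 with a lower one). The balance turned without light vector replicate 1 (33 higher, 42 lower), without dark MIF1OE replicate 2 (32 and 33) and with the 50th percentile filter (30 and 33). Higher effects prevailed under the other settings. With plant source as a fixed replicate block 211 passed, and with the sets of arrays that deviate together, chosen after the data had been seen, 374. AT1G23130 had the largest positive difference among named genes (log2 4.2, SE 0.72, limma adjusted p = 0.0227), followed by AT5G10130 (3.75, SE 0.49), the peroxidase AT1G30870 (3.5, SE 0.67), AT5G62340 (3.5, SE 0.35) and the jacalin lectin AT1G52060 (3.47, SE 0.71). AT4G37220 had the most negative (-4.01, SE 0.56), followed by AT5G39520 (-3.40, SE 0.49), AT3G48970 (-2.94, SE 0.26), the pectin methylesterase gene ATPMEPCRD (-2.69, SE 0.32) and the peroxidase AT2G37130 (-2.65, SE 0.48). AT5G39520 rose in light (2.22, SE 0.35). The calls of AT1G23130, AT1G30870, AT1G52060 and AT2G37130 ended without single arrays: 4, 9, 10 and 9 of the 12 arrays respectively (adjusted p up to 0.0640, 0.112, 0.129 and 0.0842). Those of AT1G30870 and AT1G52060 also ended without a filter, and that of AT1G52060 with the 50th percentile filter, floored values or moderated trend. Chlorophyll synthesis genes differed as a list (median -0.96, camera adjusted p = 0.00913; adjusted p = 0.259 with an estimated correlation), though none of the 3 passed over all genes and 2 were lower when adjusted over the list alone. No list was called without dark MIF1OE replicate 1. The count of 118 ranged from 58 to 192 when single arrays were left out: 75, 66, 65, 58, 60, 67 and 65 without light vector replicate 1, light MIF1OE replicate 2, dark vector replicates 1, 2 and 3, and dark MIF1OE replicates 1 and 2, and 192 without light vector replicate 3.

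Dark against light in vector seedlings gave the reference response. Photosynthesis genes were lower in darkness, 8 of 9 also when adjusted over the list alone (median -1.51, camera adjusted p = 7.404e-06; adjusted p = 0.208 with an estimated correlation). SBPASE of the Calvin cycle fell by 2.11 (SE 0.29), PSAN fell by 1.92 (SE 0.40) and PSBY fell by 1.63 (SE 0.24). CHLI2 and CHLM fell by 1.82 (SE 0.32) and 0.63 (SE 0.17), 2 of 3 chlorophyll genes (camera adjusted p = 0.0638). All 3 GH3 genes rose (GH3.3 2.1, WES1 1.91, GH3.17 1.16; camera adjusted p = 0.0341; adjusted p = 0.208 with an estimated correlation). So did 4 of 6 xyloglucan endotransglucosylases, among them XTH18 (2.87, SE 0.44), XTH19 (2.47, SE 0.74) and XTH33 (1.56, SE 0.38), with the same camera p-values. Without light vector replicate 2 only 1 list was called. EXLA2 (1.82), EXPA9 (1.59) and EXPA4 (1.59) rose among 9 expansins (adjusted p = 0.0757). IAA29 (1.40, SE 0.38) and LBD16 (1.45, SE 0.32) also rose, and the root hair gene EXPA7 fell by 1.60 (SE 0.26).

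The largest named differences in vector seedlings were AT5G44440 (5.88), ICL (5.30, SE 0.40), ATPMEPCRD (4.97), AT1G30760 (4.89) and AT1G19530 (4.79) upward in darkness, and AT1G23130 (-5.98), AT1G70820 (-5.61), AT3G05730 (-4.45), the thionin THI2.2 (-4.33) and ECS1 (-4.30) downward. BCAT4, of methionine-derived glucosinolate synthesis, fell by 3.55 (SE 0.95), COR15B fell by 1.66 (SE 0.26), and COR47 rose by 0.65 (SE 0.21). In total 4829 probe sets passed (2664 higher in darkness, 2165 lower) in vector seedlings and 3846 in MIF1OE seedlings (1968 and 1878). The balance of higher and lower depended on scaling. Median-centred arrays gave 2050 higher and 2469 lower in vector seedlings, and 1532 and 2117 in MIF1OE seedlings. Quantile normalization gave 2507 and 2400 in vector seedlings, and 1870 and 2075 in MIF1OE seedlings. The vector count was 2975 without dark vector replicate 2. Of the 31 named calls 7 ended when an array was left out, those of COR47 (adjusted p up to 0.135), IAA29 (0.0754), XTH19 (0.0905), BCAT4 (0.0530), CHLM (0.0606), GH3.17 (0.0514) and EXPA4 (0.0558). Those of CHLM and GH3.17 ended without dark vector replicate 2 and that of EXPA4 without light vector replicate 2, while the others each ended without 2 or more arrays. The call of COR47 also ended with median-centred arrays or without a filter, and that of IAA29 with only the compared arrays in the fit.

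Light-regulated genes were then followed in dark-grown MIF1OE seedlings. Of 2165 probe sets higher in light in vector seedlings, 243 were higher in dark-grown MIF1OE than in dark-grown vector seedlings (133.0 for independent lists) and 173 were lower (146.0). Of 2664 lower in light, 405 were lower in dark-grown MIF1OE (179.7) and 147 higher (163.6). Median dark effects were 0.01 and -0.21. Both differences use the dark vector arrays. The covariance across probe sets was 0.0743, of which the shared arrays give 0.0401 by the spread pooled over all arrays (simulated mean 0.0401, highest of 100 simulations 0.0433), a difference of 0.0342. That simulation leaves out the correlation of light and dark arrays of 1 source. From the dark vector arrays' own spread, less their covariance with the light arrays of the same source, the shared part was 0.0195 and the difference 0.0548. With the vector sources divided between both comparisons the covariance averaged 0.0544 over 6 divisions, and it ranged from -0.0150 to 0.147 with the sources used. These last calculations were chosen after the data had been seen. The correlation was 0.154. In the simulation of unchanged groups it was 0.50, a value fixed by equal spread and the lack of true differences. These correlations are therefore not comparable. Part of the excess of calls may come from the shared arrays.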

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

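The patterns weighed in this part and their gene lists were chosen after the results had been seen, as were the tests of seeds left in the harvest and of root share. The tests of line, scaling, spread and the shared axis, and the splits, were written down before their values were computed.

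MIF1OE changed 118 probe sets differently in darkness and light by the interaction test. The named genes with such a difference (dark effect minus light effect, log2) were AT1G23130 (4.2), AT5G10130 (3.75), AT1G30870 (3.5), AT5G62340 (3.5), AT1G52060 (3.47), EXPA7 (2.01) and AT3G56060 (1.40) upward. Downward they were AT4G37220 (-4.01), AT5G39520 (-3.40), AT3G48970 (-2.94), ATPMEPCRD (-2.69), AT2G37130 (-2.65), AT5G10210 (-2.53) and AT5G57760 (-2.18). The 3 chlorophyll synthesis genes had a median difference of -0.96, with none past the threshold over all genes and a list call that was lost with an estimated correlation (adjusted p = 0.259). Groups of 3 arrays are too small for a test of outlying samples.

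Of 19 late embryogenesis abundant genes 14 rose and 1 fell in dark-grown MIF1OE seedlings, and of 7 seed cupin and oleosin genes 5 rose and 1 fell, with both list calls lost at an estimated correlation (adjusted p = 0.0907 for each). Array scaling does not account for the shift, since the median over the 26 members was 2.26 after quantile normalization. The median was 2.73 in line 124 and 1.05 in line 127, but line 127 is 1 dark array and both lines were set against the same vector arrays, so a single line as the source stays open although the medians met the bound set for excluding it. Seeds left in the harvest or slower seedling development stay open too, because 0 members of the seed storage and oil body list had a named probe set among those tested. An effect of MIF1 on these genes is a hypothesis that cannot be told apart from these explanations.

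Of 36 class III peroxidase genes 11 rose and 3 fell in dark-grown MIF1OE seedlings, and of 7 extensin genes 4 rose, with both list calls lost at an estimated correlation (adjusted p = 0.119 and 0.154). The medians over the 43 members were 0.69 in line 124 and 0.73 in line 127, which leaves a single line as the source open for the same reasons, although they met the bound set for excluding it. A larger share of root tissue predicts that PYK10 and NAI2, abundant in roots, rise by about the overall median of 0.71. They stood at 0.15 (SE 0.16) and 0.24 (SE 0.19), below it by more than 2 SE, which goes against that prediction, while both measured root hair markers rose (EXPA7 1.56, SE 0.26, and EXPA18 1.53, SE 0.31), which goes with it. With 2 genes on each side, root share stays open. Whether the high log2 levels of PYK10 and NAI2 (12.1 and 10.8 in dark vector seedlings) limited their change was not tested.

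More probe sets were called in the dark (2052) than in the light (157). The light arrays had the larger residual SD (0.380 against 0.310), but the variance of log2 fold changes beyond error was 4.66 times larger in the dark, which argues against spread alone. Both counts also rest on the same pooled spread per probe set. A larger light spread would thus raise the SE of both comparisons alike. It could not by itself bring the light count below the dark count. With the first residual component as a covariate, the dark count was still 9.02 times the light count. That component is drawn from the residuals and leaves the fold changes unchanged, so it lowers the SE of both comparisons alike. It could hardly even out the counts, so this test decides nothing, and both counts are too high by an unknown amount. Spread alone does not account for the pattern. Nor could a shared axis of variation by way of the SE, which is the same in both comparisons. Whether such an axis shifted the group means stays open. A larger effect of MIF1OE in darkness is left as a hypothesis, found and tested on the same data.

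Other splits of the arrays are too few to decide on chance, since 3 against 3 allow 10 splits. The real split was matched or exceeded by no other in the light (157, highest other 71), in the dark (2052, highest other 0), for the interaction computed from dark minus light differences per source (211, highest other 0), and for dark against light in vector (4829, highest other 0) and MIF1OE seedlings (3846, highest other 1), so each stands at 1 of 10. Light and dark samples are paired by source, and in each genotype only 4 of the 10 dark-against-light splits part all 3 pairs, of which the 3 besides the real one called 0, while the other 6 keep both samples of at least 1 pair together. The light split with 71 calls set vector lines 1 and 4 and MIF1OE replicate 2 against the others. For the number of lists called, 1 of 10 splits did as well in light (4 lists, highest other 2), 6 of 10 in the dark (1, highest other 3), 4 of 10 for the interaction (2, highest other 4) and 3 of 10 for dark against light in vector seedlings (3, highest other 3).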

How the results depend on the processing

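The line-wise runs, the residual component, the matched sets of arrays and the other treatments of shared arrays were chosen after seeing the data. No called named gene changed sign under any alternative chosen beforehand. Total counts stayed within 1.5 times of 157, 2052, 118, 4829 and 3846 (light, dark, interaction, and dark against light in vector and MIF1OE seedlings) under quantile normalization, median-centred arrays, both pseudocount alternatives, no filter and moderated trend. The balance of directions did not always hold. In dark against light, lower probe sets outnumbered higher ones with median-centred arrays in both genotypes, and with quantile normalization in MIF1OE seedlings. Counts moved further with an adjusted p under 0.01 (49, 635, 25, 2616 and 2284), and with a 2-fold minimum in the dark and the dark-against-light comparisons (1036, 2314 and 2226), where fewer pass by construction. They also moved with the 50th percentile filter in light (103) and the interaction (63), where the cause was not tested. With only light arrays in the fit 57 passed in light, 49 of them among the 157. Fold changes are the same there, so only the spread estimate and its degrees of freedom differ. Most of the 157 light calls thus rest on the spread pooled with the dark arrays. The residual SD was larger in light (0.380) than in the dark (0.310). With only dark arrays in the fit, the dark count rose to 2418. The replicate block of 6 plant sources gave 180 in light, 1980 in darkness, 211 for the interaction, and 5843 and 4699 for dark against light; it changed no other count by over 1.5 times. Line as a random block gave 127 and 1725. MIF1OE line 124 alone gave 45 in light and 1094 in darkness, and line 127 alone 97 and 361, with fewer arrays. The first residual component as a covariate gave 329 in light, and matched sets gave 412, 3490 and 374. Both were drawn from the residuals, which makes these counts too high by an unknown amount. Leaving out single arrays gave 44 to 266 in light, 1052 to 1371 in darkness, 58 to 192 for the interaction, 2975 to 4384 for vector and 2729 to 3549 for MIF1OE seedlings. The overlap of 94 became 17 at an adjusted p under 0.01. The difference in covariance of 0.0342 was 0.0363 and 0.0296 under quantile normalization and without a filter. It was 0.0425 with the shared part from the dark vector arrays alone, 0.0548 with that part less the same-source covariance, and 0.0544 with vector sources divided (-0.0150 to 0.147 by source). Lists called (4, 1, 1 and 3 for light, dark, interaction and dark against light) became 0 in all 4 with an estimated correlation. They became 2 and 3 (light, dark) with quantile normalization, 4 and 2 (dark, interaction) with the larger pseudocount, and 0, 4, 4 and 6 without a filter. Leaving out arrays gave 0 to 4, 1 to 3, 0 to 3 and 1 to 4. Signal over background could not be set, so dim probe sets limit small changes.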

Other observations

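All lists in this part were written after the data had been seen, and the hypotheses were found in the same data. Of 19 measured late embryogenesis abundant genes, 14 rose and 1 fell in dark-grown MIF1OE seedlings (median log2 fold change 1.93, camera adjusted p = 2.962e-09; adjusted p = 0.0907 with an estimated correlation). Besides those named in the report they included LEA4-5 (2.34), DI21 (2.09) and LTI30 (1.34). In light the median was 0.70 with no member past the threshold, and the list was called up (adjusted p = 0.00813; adjusted p = 0.388 with an estimated correlation). Of 7 seed cupin and oleosin genes 5 rose and 1 fell in darkness, among them PAP85, a vicilin-type protein (3.33), while the oleosin OLEO3 fell by 1.66 (camera adjusted p = 1.483e-04; adjusted p = 0.0907 with an estimated correlation). In light their median was 1.41, with none past the threshold, and the list was called up (adjusted p = 3.356e-04; adjusted p = 0.176 with an estimated correlation). Of 36 class III peroxidases 11 rose and 3 fell in darkness (median 0.65, camera adjusted p = 5.678e-04; adjusted p = 0.119 with an estimated correlation), and 5 differed upward and 1 downward in the interaction. Of 7 extensins, which are wall glycoproteins, 4 rose in darkness, including HRGP1 (2.47), and the list was called up (adjusted p = 2.531e-04; adjusted p = 0.154 with an estimated correlation). Of 12 jacalin-related lectins 6 rose and 1 fell (adjusted p = 2.531e-04; adjusted p = 0.0907 with an estimated correlation).

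Of 111 cytosolic ribosomal protein genes 18 rose in dark-grown MIF1OE seedlings (median 0.47, adjusted p = 2.755e-16; adjusted p = 0.177 with an estimated correlation). In light their median was 0.12, with none past the threshold (adjusted p = 0.00147, and adjusted p = 0.749 with an estimated correlation). The same genes were lower in darkness than in light in vector seedlings (median -0.47, 109 of 111 below 0). In MIF1OE seedlings the median of dark against light was -0.11. The dark rise is thus measured against dark vector arrays in which these genes were low. Of 69 plastid-encoded genes 5 fell in darkness, namely psbF, psaC, psbE, psbJ and psbL, a share close to that over all probe sets (1074 of 15922). The median over the 69 was -0.47 (camera adjusted p = 3.454e-07, and adjusted p = 0.0907 with an estimated correlation). In light the median was -0.25 with none past the threshold (camera adjusted p = 3.499e-04, and adjusted p = 0.350 with an estimated correlation). In the GASA family 1 of 3 genes fell in light (AT1G22690; adjusted p = 0.00214; adjusted p = 0.149 with an estimated correlation) and 1 in darkness (AT2G14900, -1.70; adjusted p = 0.0134; adjusted p = 0.0907 with an estimated correlation). Among 38 families formed from symbol stems, only the 5 beta-tubulin genes (TUB) were called in the MIF1OE comparisons, in darkness (median -0.68, 2 lower, adjusted p = 0.0316; adjusted p = 0.462 with an estimated correlation). In dark against light in vector seedlings CRR genes (median -1.02) and PRA genes (median 0.52) were called at the preset correlation (adjusted p = 0.00519 and 0.0423) and not with an estimated one (0.397 for both).

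The arrays also vary along an axis that crosses the groups. In both light and darkness, deviations from group means matched vector line 1 with MIF1OE replicate 2 (r 0.541 and 0.448), vector line 4 with MIF1OE replicate 1 (0.516 and 0.495) and vector line 7 with MIF1OE line 127 (0.445 and 0.253), more than any other match. The first component of these deviations held 32.1% of their variance. GI, a clock gene whose level depends on the time of day, loaded most among named genes. It was at 4.76 and 5.11 on the light arrays of vector line 7 and MIF1OE line 127 and between 8.02 and 8.83 on the other light arrays. The labels give no batch, and no explanation was tested. With these matched sets as a block, 412 probe sets passed in light, 3490 in darkness and 374 in the interaction, and all 157, 2052 and 118 of the original calls were among them. The sets were drawn from the residuals themselves, which makes these counts too high by an unknown amount.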
